A study of Mus musculus with 8 samples.

How the data were processed

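The 8 libraries were made with the SMARTer Stranded Total RNA-Seq (Pico) kit and sequenced on an Illumina HiSeq, per the labels. Brains had been dissociated enzymatically, cells sorted on a FACS Aria and RNA taken with RNeasy Plus kits. The submitters name TopHat and TopHat2 without a version, Cufflinks 2.2.1 and HTSeq 0.11.2, with the mouse genome build mm10. Which aligner served which step, the strand setting and the annotation are not given in the sources used here. A table of raw counts per gene symbol, deposited by the authors and matching whole-number counts from HTSeq, held 17261 genes. A second table, deposited by the authors, held FPKM (fragments scaled to gene length and library total, matching Cufflinks output) for 23827 genes. The tables shared 17026 symbols, after a leading space was taken off 24 symbols of the count table. As dates stood 23 symbols of the FPKM table, which were left unmatched. No reads were realigned. All 8 columns of each table were matched to a library by the labels.

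Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group, with a minimum count of 10 in a library of median size and a minimum total of 15, which left 11955. Libraries were scaled by TMM factors, and CPM were taken over the scaled totals. All 8 libraries, in 4 groups of 2, were fitted in 1 quasi-likelihood model with a mean per group, so that the groups shared 1 estimate of the spread, with 4 residual degrees of freedom. The 7 comparisons were dMCAO against sham in young and in aged mice, aged against young in sham and in dMCAO mice, the interaction, age averaged over both surgeries and dMCAO averaged over both ages. Tests were two-sided, p was adjusted by Benjamini and Hochberg over all tested genes of a comparison, and adjusted p under 0.05 was called. This was also done over each list alone. Other tools were DESeq2 1.42.0 and limma 3.58.1, as limma-voom, as voom with a quality weight per library, and as limma-trend on FPKM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

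The comparisons, the model, the lists and the rule for named genes were fixed before the data were examined. The 32 lists hold genes of microglial state (homeostatic, disease-associated), interferon, antigen presentation, chemokines and chemotactic receptors, angiogenesis, inflammatory cytokines and NF-kB targets, alternative activation, complement, lysosome, lipid handling, cell cycle, senescence, oxidative phosphorylation, glycolysis and hypoxia, ribosomal proteins, immediate early and dissociation response and extracellular matrix. They also hold markers of border-associated macrophages, monocytes, neutrophils, T and NK cells, B cells, dendritic cells, neurons, astrocytes, oligodendrocytes, endothelial and mural cells, ependymal and choroid plexus, and erythroid cells, with nuclear and mitochondrial RNA and sex-linked genes as checks. Limma's camera tested the 26 lists with at least 5 tested members at a preset correlation of 0.01, adjusted over a comparison's lists. Beside it stand camera with correlation estimated per list and fry, which tests if a list moves 1 way on balance, not against other genes.

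Genes were named by a rule. Per comparison it took up to 10 higher and 10 lower called genes with the largest log2 fold change, a mean of at least 10 CPM and no overlap between the libraries of the groups, leaving out predicted genes and pseudogenes. For the interaction, the difference between dMCAO and sham had to have opposite signs or sizes at least 2-fold apart at the 2 ages. It further took up to 4 members of each list with the smallest adjusted p, and, where under 5 genes were called, the 5 genes of at least 10 CPM with the smallest p. A gene named in 1 comparison could be given in others. Nlrp1c-ps and Lars2 fall outside the rule and were chosen after their values were seen.

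A group with no counts was set at 3 counts over the group, which gives a bound of at least that fold. For 1 to 3 counts the ratio carries an exact binomial 95% interval. Medians of lists holding such genes are also given with those genes at their bound. Shares carry Wilson intervals. These intervals and floors cover counting error only, since molecular identifiers are not given in the sources used here. Gene positions and exon lengths came from GENCODE mouse release M21 and covered 96.5% of the tested genes.

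Alternatives were RLE or upper-quartile factors, DESeq2, limma-voom, robust edgeR, no filter, a filter at a mean of 5 CPM, only the 2 groups compared, a replicate block by number or by the N code of the titles, an added threshold of 1 on the absolute log2 fold change, and FPKM with a pseudocount of 1 or 0.1 and a mean of at least 1 or no filter. Added after the data were seen were quality weights per library, thinning to the smallest total, Rn45s or the 3 shallow libraries left out, and the FPKM table less its young sham 1 column. Each library was also left out in turn, where the lone library of a group is assumed to vary like the other groups. The procedure was tested on simulated data with 200 genes at log2 fold changes of 1, 2 or 3. At 1, 2 and 3 it recovered 0, 14.9 and 53.0% of these for dMCAO in young, 2.99, 20.9 and 40.9% for dMCAO in aged, 0, 0 and 28.8% for age in sham, 0, 22.4 and 43.9% for age after dMCAO, 0% at each size for the interaction, 2.99, 40.3 and 71.2% for age averaged and 0, 56.7 and 71.2% for dMCAO averaged. False calls were 1 of 46, 1 of 44, 0 of 19, 6 of 50, 0 of 0, 6 of 82 and 4 of 90, in this order. The shifted list was missed for dMCAO in young and the interaction (adjusted p = 0.163 and 0.339), with 1 other list called, for age averaged. With young libraries only it recovered 56.7, 94.0 and 100% at 1, 2 and 3, with 15 false calls of 182. Rates with spread as unequal between the ages as here were not tested.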

Results

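RNA was sequenced from microglia that had been sorted as CD45 intermediate, CD11b positive cells from the brains of male C57BL/6 wild-type mice. The young mice were 10 weeks old and the aged mice 18 months old. Each age had a sham operation or distal middle cerebral artery occlusion (dMCAO), a model of stroke in which a branch of the artery over the cortex is closed, and the brains were taken after 14 days. The 8 libraries fall into 4 groups with n = 2 each: young sham, young dMCAO, aged sham and aged dMCAO. The title of the series asks how age alters the attraction of cells and the stimulation of vessel growth by microglia during recovery from stroke, so the lists of chemokines and of angiogenesis factors bear on its question directly. Levels are given in CPM, counts scaled to the total of the library, as mean ± SD over the 2 libraries of a group, and log2 fold changes as estimate ± SE, in parentheses where they follow levels. For a list, the number of its tested members with a log2 fold change above 0 is given with the median log2 fold change.

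Depth differed between the ages. The young sham libraries held 5767387 and 4645303 counts and the young dMCAO libraries 4181698 and 5058884. The aged sham libraries held 1484870 and 5124213 and the aged dMCAO libraries 747637 and 1297568, so 3 of the 4 aged libraries were shallow. Genes with at least 1 count numbered 13711, 14469, 13644 and 13990 in the young libraries and 10473, 13322, 9126 and 9888 in the aged ones, in the same order. A count of 0 allows up to 3 counts, which is 0.474, 0.594, 0.657 and 0.559 CPM in the young libraries and 2.15, 0.511, 4.29 and 3.28 CPM in the aged ones. The ribosomal RNA precursor Rn45s took 4.30, 8.60, 3.44 and 4.60% of the counts of the young libraries and 12.7, 4.04, 13.4 and 34.3% of those of the aged. Malat1, a nuclear RNA, took 2.48, 2.16, 2.14 and 1.88% in the young and 1.34, 1.81, 0.341 and 0.468% in the aged libraries. Lars2, the mitochondrial leucyl transfer RNA synthetase, took 0.352, 0.897, 0.311 and 0.410% in the young and 4.58, 0.356, 3.55 and 4.09% in the aged libraries. The 95% Wilson intervals of these shares reach at most 0.0817 percentage points to either side.

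Replicates resembled each other less in the aged groups. Across genes, the log2 CPM of the 2 libraries correlated with Pearson's r = 0.961 in young sham, 0.963 in young dMCAO, 0.744 in aged sham and 0.696 in aged dMCAO, where genes are not independent replicates. The biological coefficient of variation was 0.570 over all 8 libraries, 0.198 in the 4 young libraries alone and 0.751 in the 4 aged ones. Between the groups of a comparison the median log2 fold change of all 11955 tested genes was 0.00 for dMCAO in young mice and −0.02 for age in sham mice. It was −0.29 for dMCAO in aged mice, −0.32 for age after dMCAO, −0.36 for the interaction, −0.24 for age averaged over the surgeries and −0.15 for dMCAO averaged over the ages. Under upper-quartile scaling 101 of the 101 list results described here kept their direction and call, and under RLE scaling 100 did. With an estimated correlation between genes, 4 of the 20 list calls for dMCAO in young mice held (disease-associated microglia, interferon, chemokines and choroid plexus), and 0 of those in the other 6 comparisons. In the fit of only the 4 young libraries 20 lists were called too, and 0 of them held.

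Markers of other cells were present at uneven levels beside the genes of homeostatic microglia. Genes of the homeostatic list summed to 26947, 28013, 21491 and 23771 CPM in the young libraries, and to 23289, 8681, 26009 and 18362 CPM in the aged ones. The 8681 CPM of aged sham 2 was the lowest of the 8. Monocyte markers in that library summed to 6079.6 CPM, against 330.2 to 1788 CPM in the other 7, B cell markers to 208 CPM against 0 to 19.7, and T and NK cell markers to 141 CPM against 5.85 to 28.4. Markers of ependymal cells and choroid plexus (choroid plexus below), the cells that line the ventricles and make cerebrospinal fluid, summed to 5333 and 3623 CPM in aged dMCAO, 11.8 and 5.40 in young dMCAO, 117 and 386 in young sham, and 896 and 369.7 in aged sham. Neutrophil markers summed to 721 and 871 CPM in aged dMCAO and to 1257 to 2105 CPM in the other 6 libraries. Neuron markers summed to 4.82 to 29.5 CPM in 7 libraries and to 113 CPM in aged dMCAO 1. Astrocyte markers reached 502 and 490.0 CPM and oligodendrocyte markers 1509 and 1202 CPM in aged dMCAO, against 62.5 to 278 and 454 to 1196 CPM elsewhere. The 1 erythroid marker in the table reached at most 11.45 CPM, and the sex-linked genes of the sample check summed to 66.7 to 219 CPM.

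The first comparison asked what stroke changed in microglia of young mice after 14 days. Spp1, which codes for the secreted matrix protein osteopontin, rose from 3.42 ± 2.16 to 222 ± 3.66 CPM (6.03 ± 0.56, adjusted p = 0.0231), and both dMCAO libraries lay above both sham libraries. It lies on chromosome 5, 104435118 to 104441050 of the mm10 build. Other genes of the disease-associated state had large estimates that did not pass alone. Cst7, an inhibitor of cathepsins, measured 86.2 ± 14.8 against 2.02 ± 1.17 CPM (5.37 ± 0.63, adjusted p = 0.0805), and Lpl, lipoprotein lipase, 74.1 ± 38.5 against 10.3 ± 1.71 CPM (2.84 ± 0.44, adjusted p = 0.280). Gpnmb, a glycoprotein of lipid-laden macrophages, had 247 counts after dMCAO and 1 after sham, a ratio of 283 with a 95% interval of 50.3 to 11217 (adjusted p = 0.280). Apoe, which carries cholesterol, measured 8902 ± 719 against 1262 ± 496 CPM (2.82 ± 0.63, adjusted p = 0.982). As a list, the genes of disease-associated microglia rose: 23 of 23 above 0, median 1.51, adjusted p = 1.92e-84, adjusted p = 0.0133 with estimated correlation. Adjusted over the list alone, 10 of the 23 were higher, and 1 over all genes.

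Genes that answer to interferon rose together, with 27 of 27 above 0, median 1.88, adjusted p = 2.05e-49, adjusted p = 0.0133 with estimated correlation, and 6 of the 27 were higher when adjusted over the list alone. Irf7, a driver of interferon production, measured 59.4 ± 7.90 against 9.20 ± 1.84 CPM (2.69 ± 0.63, adjusted p = 1.000), and Ifi27l2a 21.3 ± 2.71 against 3.54 ± 1.44 CPM (2.58 ± 0.56, adjusted p = 0.895). Chemokines and their receptors (chemokines below) rose as a list (23 of 27 above 0, median 0.80, adjusted p = 5.97e-10, adjusted p = 0.0133 with estimated correlation), with 0 members called alone. Cxcl16 measured 173 ± 61.3 against 80.6 ± 4.89 CPM, Ccl3 635 ± 90.03 against 243 ± 47.1 CPM and Cxcl10 21.9 ± 6.19 against 5.95 ± 1.41 CPM, and none of the 3 passed (adjusted p = 1.00 for each). Angiogenesis factors rose too (24 of 29 above 0, median 0.80, adjusted p = 2.37e-18, adjusted p = 0.0503 with estimated correlation). Spp1 belongs to that list and was the 1 member called when adjusted over the list alone. Igf1, a growth factor, measured 29.2 ± 7.92 against 4.71 ± 5.10 CPM, and Hif1a, the regulator of the response to low oxygen, 234 ± 51.1 against 141 ± 3.605 CPM, neither passing.

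Inflammatory cytokines and targets of NF-kB rose as a list (20 of 22 above 0, median 1.06, adjusted p = 9.22e-25, adjusted p = 0.0503 with estimated correlation), with 0 members called over the list alone. Il1b measured 150.3 ± 10.4 against 30.6 ± 0.661 CPM, Tnf 127 ± 44.4 against 44.4 ± 19.9 CPM and the adhesion molecule Icam1 420.4 ± 96.4 against 204 ± 59.99 CPM, none passing. The lists that rose further were antigen presentation, complement, lysosome, lipid handling and senescence, with 16 of 19, 10 of 13, 22 of 28, 19 of 26 and 5 of 10 members above 0 and medians of 0.54, 0.17, 0.19, 0.19 and 0.11. These passed with adjusted p from 4.54e-08 to 0.0498, adjusted p from 0.0937 to 0.417 with estimated correlation. Of their members, H2-D1 and H2-K1, which present peptides on major histocompatibility class I, measured 142 ± 0.247 against 41.7 ± 0.436 CPM and 740.1 ± 18.6 against 314 ± 91.9 CPM. Rising as well were glycolysis, ribosomal proteins, immediate early and dissociation genes and extracellular matrix, with 19 of 22, 42 of 46, 19 of 24 and 18 of 26 members above 0 and medians of 0.30, 0.24, 0.89 and 0.58. These had adjusted p from 3.39e-09 to 7.24e-05, adjusted p from 0.0563 to 0.365 with estimated correlation. Adjusted over the list alone, members called were 1 higher of antigen presentation, 1 higher of lysosome, 4 higher of lipid handling and 2 lower of immediate early and dissociation genes. That list also holds genes that answer to dissociation, and the part of dissociation in the rise of cytokines and chemokines was not tested. Its 2 lower members were the heat shock genes Hspa1a, with 477 ± 70.2 against 1453 ± 429 CPM (−1.61 ± 0.32, adjusted p = 0.892), and Hspa1b, with 581 ± 19.2 against 1815 ± 587 CPM (−1.64 ± 0.34, adjusted p = 0.892).

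Genes of the resting state fell as a list. Homeostatic genes had 1 of 16 above 0, median −0.34, adjusted p = 3.25e-05, adjusted p = 0.301 with estimated correlation, and 0 were called alone. The purine receptors P2ry12 and P2ry13 measured 853 ± 82.9 against 1189 ± 74.1 CPM and 422 ± 32.1 against 562 ± 23.7 CPM, with log2 fold changes of −0.48 ± 0.33 and −0.41 ± 0.27. Among markers of other cells, those that rose were monocytes and neutrophils, with 12 of 13 and 10 of 11 members above 0 and medians of 1.34 and 0.34. These gave adjusted p = 2.75e-07 and 0.00142, adjusted p = 0.251 and 0.251 with estimated correlation. Those that fell were border macrophages, astrocytes and choroid plexus, with 2 of 11, 2 of 9 and 0 of 6 members above 0 and medians of −0.59, −1.53 and −5.27 (−3.95 with bounds). They had adjusted p from 7.49e-37 to 0.0152, adjusted p from 0.0133 to 0.293 with estimated correlation. Of the choroid list 4 members were lower when adjusted over the list alone, and 0 over all genes. Ttr, the thyroid hormone carrier made by the choroid plexus, measured 4.67 ± 4.23 against 167 ± 138 CPM (−5.18 ± 0.90, adjusted p = 0.488), and Enpp2, the enzyme autotaxin, 2.35 ± 0.695 against 69.6 ± 39.4 CPM (−4.88 ± 0.74, adjusted p = 0.280). The 6 other tested lists were not called (adjusted p from 0.0954 to 0.869), of which cell cycle had a median of −0.13 with a test pointing up.

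The test over all 8 libraries called 1 gene higher and 0 lower with edgeR, 148 genes having an unadjusted p under 0.05, with DESeq2 calling 32. With only the 4 young libraries, whose spread was smaller, 160 genes were higher and 13 lower, and Spp1, Apoe, Il1b and Irf7 had adjusted p = 5.96e-07, 7.59e-05, 3.43e-05 and 9.77e-05 there. The call for Spp1 ended without young sham 1, young dMCAO 2 or any 1 of the 4 aged libraries, with the log2 fold change between 5.44 and 6.82 and adjusted p of at most 0.168. List calls ended without young sham 1 for complement (median −0.02, −0.04 with bounds), lysosome, senescence (median −0.07), ribosomal proteins (median −0.06), monocytes and neutrophils; without young sham 2 for complement, immediate early and dissociation genes, border macrophages (median 0.28) and astrocytes (median 0.06, 0.02 with bounds); without young dMCAO 2 for complement (median −0.08, 0.09 with bounds), lysosome, senescence (median −0.02) and glycolysis; without any 1 of the 4 aged libraries for complement and senescence, with adjusted p from 0.0533 to 0.993, where a median is given, here and below, if its sign changed. Without young sham 1 the tests of ribosomal proteins and neutrophils (median 0.17) turned down. Under the block by N code, calls ended for homeostatic microglia (median 0.01), antigen presentation (median −0.05), lipid handling (median −0.07), senescence (median −0.03), border macrophages and monocytes, with adjusted p from 0.0817 to 0.841.

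The second comparison asked the same question in aged mice. Spp1 rose from 20.5 ± 9.49 to 496 ± 79.1 CPM (4.65 ± 0.52, adjusted p = 0.0401). Genes that fell were Sgms1, Ralgapa1 and Btaf1. Sgms1 makes the membrane lipid sphingomyelin, and it had 3 counts after dMCAO against 628 after sham, 46.4-fold lower with a 95% interval of 15.8 to 226 (adjusted p = 0.0463). Ralgapa1, part of a complex that turns off Ral GTPases, fell from 118 ± 7.16 to 7.74 ± 3.21 CPM (−3.96 ± 0.44, adjusted p = 0.0401). Btaf1, which removes TATA-binding protein from DNA, fell from 122 ± 8.51 to 9.72 ± 4.46 CPM (−3.68 ± 0.42, adjusted p = 0.0401). These genes lie on chromosome 19, 32122727 to 32389714, chromosome 12, 55602896 to 55821167 and chromosome 19, 36926079 to 37012752, and their exon lengths are 10546, 12315 and 10259 bases. Malat1 took 0.341 and 0.468% of the counts in aged dMCAO against 1.34 and 1.81% in aged sham, and Rn45s 13.4 and 34.3% against 12.7 and 4.04%. Vps13b, a lipid transfer protein with a long transcript, had the fifth smallest p and did not pass, measuring 26.9 ± 3.69 against 215 ± 74.9 CPM (−3.00 ± 0.37, adjusted p = 0.0528).

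Genes of disease-associated microglia rose as a list here too (17 of 23 above 0, median 0.94, adjusted p = 2.55e-09, adjusted p = 0.261 with estimated correlation), with 4 higher over the list alone and 1 over all genes. Lpl, Cst7 and Gpnmb had log2 fold changes of 2.81 ± 0.43, 3.59 ± 0.58 and 3.55 ± 0.90 with adjusted p = 0.0995, 0.0995 and 0.141. Other lists that rose were interferon-stimulated genes, lysosome, glycolysis and immediate early and dissociation genes, with 21 of 27, 20 of 28, 15 of 22 and 24 of 24 members above 0 and medians of 0.65, 0.28, 0.62 and 0.75. These had adjusted p from 2.55e-09 to 0.0150, adjusted p from 0.261 to 0.802 with estimated correlation. Members called over the list alone were 1 lower of lysosome, 2 higher of glycolysis and 2 higher of immediate early and dissociation genes. The last 2 were Hspa1b and Hspa1a, with 1.66 ± 0.34 and 1.49 ± 0.33 and adjusted p = 0.126 and 0.126. Inflammatory cytokines were called up (14 of 22 above 0, median 0.39, adjusted p = 0.0288, adjusted p = 0.706 with estimated correlation) although their mean was −0.97, with 1 higher and 2 lower over the list alone.

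The lists nearest to the title of the series were not called in aged mice. Chemokines had 11 of 27 above 0, median −0.63, adjusted p = 0.811, adjusted p = 0.802 with estimated correlation, and angiogenesis factors 14 of 29 above 0, median −0.19, adjusted p = 0.198, adjusted p = 0.802 with estimated correlation, with a mean of −0.98 and a test pointing up. Ccl2, which draws monocytes, had 1 count after dMCAO and 266 after sham, 59.0-fold lower with a 95% interval of 10.5 to 2339.7 (adjusted p = 0.0995). Its receptor Ccr2 measured 6.56 ± 9.28 against 178 ± 217 CPM (−4.67 ± 1.42, adjusted p = 0.168), high only in aged sham 2. Hif1a measured 362 ± 34.3 against 148 ± 6.60 CPM (1.29 ± 0.29, adjusted p = 0.126). Lists that fell were antigen presentation, alternative activation and cell cycle, with 3 of 19, 4 of 13 and 4 of 28 members above 0 and medians of −0.86, −0.66 and −2.42. These had adjusted p from 0.0288 to 0.0480, from 0.261 to 0.802 with estimated correlation. The class II genes H2-Ab1 measured 110.4 ± 13.8 against 603 ± 522 CPM (−2.45 ± 0.59, adjusted p = 0.140) and H2-Eb1 had −2.88 ± 0.63 (adjusted p = 0.126). Over the list alone, 3 members each of antigen presentation and alternative activation were lower.

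Markers of other myeloid cells fell: border macrophages, monocytes and neutrophils, with 1 of 11, 1 of 13 and 1 of 11 members above 0 and medians of −2.70 (−2.29 with bounds), −4.01 and −3.33 (−2.60 with bounds). The tests gave adjusted p from 8.66e-07 to 0.0145, adjusted p from 0.261 to 0.558 with estimated correlation. S100a9, abundant in neutrophils, measured 16.9 ± 11.7 against 323 ± 36.1 CPM (−4.22 ± 0.76, adjusted p = 0.113). Vcan, a proteoglycan of monocytes, had 1 count against 657, 146-fold lower (95% interval 26.1 to 5766, adjusted p = 0.126). Markers of astrocytes, oligodendrocytes and choroid plexus rose, with 6 of 9, 6 of 7 and 5 of 6 members above 0. Medians were 1.11, 1.35 and 2.10. Tests had adjusted p from 0.000896 to 0.0181, from 0.261 to 0.468 with estimated correlation. Ttr and Enpp2 measured 3518 ± 631 against 443 ± 282 CPM (2.99 ± 0.78, adjusted p = 0.143) and 828 ± 625 against 154 ± 61.0 CPM (2.43 ± 0.62, adjusted p = 0.143). Over the list alone, 4 border macrophage, 6 monocyte and 9 neutrophil markers were lower, and 1 oligodendrocyte and 2 choroid markers higher. The 9 other tested lists were not called (adjusted p from 0.0635 to 0.927).

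Of the 11955 genes, 1 passed as higher and 3 as lower, and 0 passed in edgeR when the 4 aged libraries were fitted alone, where 555 had an unadjusted p under 0.05. DESeq2 called 1034. The count was 1 without young sham 1, 1 without young sham 2, 0 without young dMCAO 1, young dMCAO 2 or aged sham 2, 78 without aged sham 1, 402 without aged dMCAO 1 and 422 without aged dMCAO 2. List calls ended without aged sham 2 for antigen presentation, lysosome, cell cycle (median 0.00, 0.51 with bounds), glycolysis, monocytes, astrocytes, oligodendrocytes and choroid plexus; without aged dMCAO 1 for antigen presentation, inflammatory cytokines, alternative activation, cell cycle and border macrophages; without aged sham 1 for inflammatory cytokines, alternative activation and border macrophages; without young dMCAO 2 for alternative activation; without aged dMCAO 2 for alternative activation, lysosome (median −0.04), border macrophages and astrocytes (median −0.14, 0.59 with bounds), with adjusted p from 0.0511 to 0.879. Without aged sham 2 the median of the monocyte markers was −1.59, −1.54 with bounds. The block by N code ended those of antigen presentation, alternative activation, lysosome, cell cycle, astrocytes and choroid plexus, with adjusted p from 0.0574 to 0.268.

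The comparison of sham-operated mice asked how aged microglia differed without stroke. No gene passed, so levels and estimates are given for those with the smallest p and for list members. Hspa1b and Hspa1a, inducible heat shock proteins, measured 211 ± 60.5 against 1815 ± 587 CPM (−3.10 ± 0.36, adjusted p = 0.101) and 205 ± 11.4 against 1453 ± 429 CPM (−2.82 ± 0.34, adjusted p = 0.101). Hsph1, their partner, had −2.51 ± 0.33, P3h2, a collagen-modifying enzyme, −2.35 ± 0.33, and Tpm4, an actin-binding tropomyosin, 2.73 ± 0.39, with adjusted p = 0.138, 0.160 and 0.160. Homeostatic genes fell as a list (1 of 16 above 0, median −1.03, adjusted p = 3.45e-12, adjusted p = 0.243 with estimated correlation), and 7 of them were lower over the list alone. P2ry13 and Gpr34 measured 168 ± 31.4 against 562 ± 23.7 CPM (−1.74 ± 0.28, adjusted p = 0.219) and 147 ± 12.5 against 489 ± 65.1 CPM (−1.73 ± 0.32, adjusted p = 0.269).

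Disease-associated genes rose (19 of 23 above 0, median 2.30, adjusted p = 1.93e-15, adjusted p = 0.158 with estimated correlation), with 13 higher over the list alone. Clec7a, a receptor for fungal glucans, measured 117 ± 65.7 against 13.2 ± 5.21 CPM (3.16 ± 0.57, adjusted p = 0.269). Fabp5, Lpl and Spp1 had log2 fold changes of 4.68 ± 0.87, 2.19 ± 0.43 and 2.54 ± 0.51 with adjusted p = 0.269, 0.270 and 0.270. Interferon-stimulated genes rose (27 of 27 above 0, median 1.80, adjusted p = 3.76e-14, adjusted p = 0.158 with estimated correlation), with 10 higher over the list alone. Ifi27l2a measured 50.1 ± 0.939 against 3.54 ± 1.44 CPM (3.82 ± 0.58, adjusted p = 0.212) and Irf7 2.57 ± 0.63 as log2 fold change (adjusted p = 0.2999). Genes of antigen presentation rose (17 of 19 above 0, median 1.38, adjusted p = 2.55e-09, adjusted p = 0.243 with estimated correlation), with 6 higher over the list alone. H2-Ab1 measured 603 ± 522 against 63.8 ± 13.4 CPM (3.24 ± 0.60, adjusted p = 0.269) and H2-Eb1 had 3.28 ± 0.63 (adjusted p = 0.269).

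Ribosomal protein genes rose, with 44 of 46 above 0, median 1.24, adjusted p = 5.65e-38, adjusted p = 0.158 with estimated correlation, and 38 of the 46 were higher over the list alone. Rplp0, Rpsa and Rpl4 had 1.57 ± 0.29, 1.66 ± 0.34 and 1.33 ± 0.28 with adjusted p = 0.269, 0.270 and 0.270. Chemokines rose (21 of 27 above 0, median 1.15 (1.11 with bounds), adjusted p = 0.00854, adjusted p = 0.178 with estimated correlation), with 0 members called alone. A further group that rose held the lists for angiogenesis, lipid handling, cell cycle, oxidative phosphorylation, glycolysis and extracellular matrix, with 20 of 29, 20 of 26, 26 of 28, 34 of 39, 15 of 22 and 14 of 26 members above 0 and medians of 0.93, 0.76, 2.00, 0.53, 0.61 and 0.24 (0.66 with bounds). Tests of these gave adjusted p from 3.20e-05 to 0.00414, adjusted p from 0.158 to 0.481 with estimated correlation. Immediate early and dissociation genes fell (7 of 24 above 0, median −0.48, adjusted p = 9.71e-05, adjusted p = 0.322 with estimated correlation). Over the list alone, members called were 1 higher of angiogenesis, 4 higher of lipid handling, 3 higher of glycolysis, 1 higher of extracellular matrix and 4 lower of immediate early and dissociation genes. Beside these changes, the markers that rose were those of monocytes and neutrophils, with 13 of 13 and 9 of 11 members above 0 and medians of 3.40 and 1.004. They came with adjusted p = 1.10e-09 and 0.00197, adjusted p = 0.243 and 0.243 with estimated correlation. Monocyte markers had 7 members higher over the list alone. Plac8 and Ccr2 measured 98.5 ± 123 against 2.52 ± 2.89 CPM (5.32 ± 1.55, adjusted p = 0.352) and 178 ± 217 against 10.2 ± 5.48 CPM (4.14 ± 1.29, adjusted p = 0.391), the high values being those of aged sham 2. The 11 other tested lists were not called (adjusted p from 0.0511 to 0.647).

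The count was 0 in edgeR, with 1129 genes at an unadjusted p under 0.05 and 384 calls by DESeq2. Without aged sham 1 the count was 4. Without the 3 shallow libraries, which leaves aged sham 2 as the lone aged library, it was 3495. List calls ended without aged sham 1 for chemokines and extracellular matrix; without aged sham 2 for cell cycle (median −0.59, −0.38 with bounds); without young sham 1 for oxidative phosphorylation, immediate early and dissociation genes (median 0.18), extracellular matrix (median 0.00, 0.56 with bounds) and neutrophils, with adjusted p from 0.0503 to 0.992.

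The comparison after dMCAO asked how aged microglia differed from young ones after stroke. The 2 genes that rose are markers of the choroid plexus. Ttr, on chromosome 18, 20665280 to 20674321, rose from 4.67 ± 4.23 to 3518 ± 631 CPM (9.57 ± 1.07, adjusted p = 0.0275), and Enpp2, on chromosome 15, 54838901 to 54952892, from 2.35 ± 0.695 to 828 ± 625 CPM (8.45 ± 0.84, adjusted p = 0.0221). Ccl2, on chromosome 11, 82035571 to 82037453, fell, with 1 count in aged and 936 in young dMCAO, 152-fold lower with a 95% interval of 27.2 to 6009.8 (adjusted p = 0.0366). Cmya5, a large protein best known from muscle, had 2 against 596 counts, 48.4-fold lower (95% interval 13.3 to 401, adjusted p = 0.0366). Btaf1 and Ralgapa1 fell from 196 ± 0.0907 to 9.72 ± 4.46 CPM (−4.36 ± 0.42, adjusted p = 0.0221) and from 119 ± 2.66 to 7.74 ± 3.21 CPM (−3.96 ± 0.44, adjusted p = 0.0275). Vps13b and the receptor phosphatase Ptprs fell from 190.5 ± 14.8 to 26.9 ± 3.69 CPM (−2.82 ± 0.37, adjusted p = 0.0458) and from 168 ± 22.8 to 27.1 ± 1.90 CPM (−2.62 ± 0.33, adjusted p = 0.0366). The ninth gene, the pseudogene Nlrp1c-ps, had 2 against 1201 counts, 97.51-fold lower (95% interval 26.9 to 806, adjusted p = 0.0366). Malat1 took 0.341 and 0.468% of the counts in aged against 2.14 and 1.88% in young dMCAO, Rn45s 13.4 and 34.3% against 3.44 and 4.60%, and Lars2 3.55 and 4.09% against 0.311 and 0.410%, and RNA quality was not tested as a cause. In each of the 9, both aged libraries lay on the same side of both young ones.

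Markers of other brain cells rose as lists. These were the markers of choroid plexus, astrocytes and oligodendrocytes, with 5 of 6, 7 of 9 and 5 of 7 members above 0 and medians of 9.62 (7.72 with bounds), 4.06 and 2.72. They gave adjusted p from 1.01e-14 to 4.11e-05, adjusted p from 0.171 to 0.240 with estimated correlation. Members called over the list alone were 5 higher of choroid plexus, 6 higher of astrocytes and 4 higher of oligodendrocytes. Lists of cell state that rose were disease-associated microglia, interferon-stimulated genes, oxidative phosphorylation, glycolysis and ribosomal proteins, with 19 of 23, 22 of 27, 25 of 39, 16 of 22 and 45 of 46 members above 0 and medians of 0.56, 0.94, 0.48, 0.73 and 1.04. Their tests gave adjusted p from 5.25e-24 to 0.00571, adjusted p from 0.171 to 0.465 with estimated correlation. Over the list alone, members called were 1 higher of disease-associated microglia, 4 higher of glycolysis and 26 higher of ribosomal proteins.

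Neutrophil markers fell (0 of 11 above 0, median −2.58 (−1.70 with bounds), adjusted p = 7.37e-05, adjusted p = 0.240 with estimated correlation), with 7 of them lower over the list alone. S100a9 measured 16.9 ± 11.7 against 203 ± 28.1 CPM (−3.55 ± 0.75, adjusted p = 0.0943). Chemokines were not called (10 of 27 above 0, median −0.30, adjusted p = 0.625, adjusted p = 0.796 with estimated correlation), with Ccl2 the 1 member lower over all genes and 2 lower over the list alone. Angiogenesis factors were not called either (14 of 29 above 0, median −0.11, adjusted p = 0.437, adjusted p = 0.957 with estimated correlation), and their mean was −0.70 with a test pointing up. Homeostatic genes had 2 of 16 above 0, median −0.65, adjusted p = 0.0868, adjusted p = 0.895 with estimated correlation, with 3 lower over the list alone. In all, 17 tested lists were not called (adjusted p from 0.0868 to 0.947).

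With 2 genes higher and 7 lower in edgeR, 2343 genes had an unadjusted p under 0.05, and DESeq2 called 1207. The count fell to 4 under RLE scaling, and to 0 with only the 4 dMCAO libraries in edgeR, where 2195 genes had an unadjusted p under 0.05. It was 3 without young sham 1 or young sham 2, 0 without young dMCAO 1 or young dMCAO 2, 242 without aged sham 1, 201 without aged sham 2, 692 without aged dMCAO 1 and 486 without aged dMCAO 2. The 9 called lists kept their call when each of the 8 libraries was left out in turn.

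**Figure D1:**
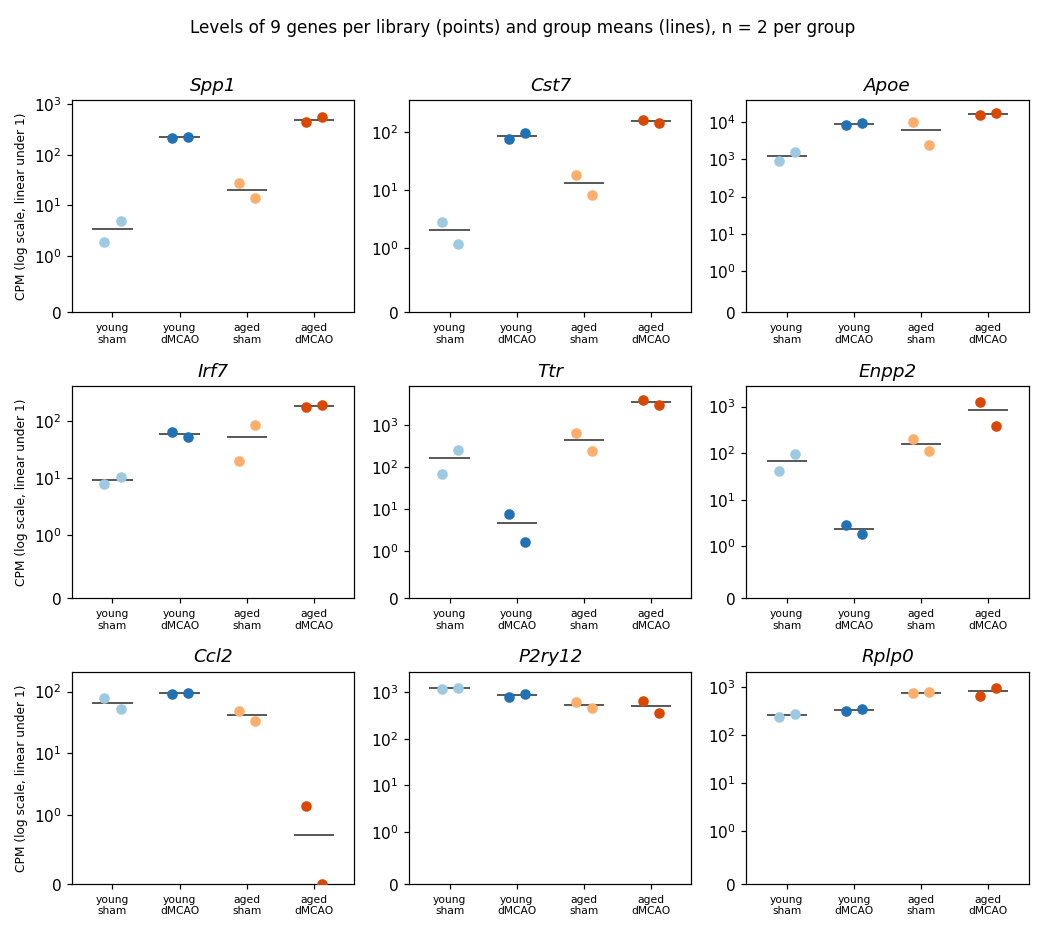
Level of 9 genes in each of the 8 libraries, in CPM on a log axis that is linear under 1, by group, with a point per library and a line at each group mean (n = 2). Spp1 averaged 3.42 and 20.5 CPM in the sham groups and 222 and 496 CPM after dMCAO, and Ttr averaged 3518 CPM in aged dMCAO and 4.67 CPM in young dMCAO.

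The interaction asked whether the response to dMCAO itself differed between the ages. It was not called for any gene, so a gene called at 1 age and not at the other is not shown to differ between them. The smallest adjusted p was 0.154, shared by Enpp2, Ralgapa1, Btaf1, Hspa1b, Ttr and Hspa1a. Their interaction log2 fold changes were 7.31 ± 0.97, −4.14 ± 0.56, −3.81 ± 0.53, 3.30 ± 0.48, 8.17 ± 1.19 and 3.10 ± 0.46. Hspa1b measured 581 ± 19.2 against 1815 ± 587 CPM after dMCAO and sham in young mice and 667 ± 43.4 against 211 ± 60.5 CPM in aged mice. Spp1 had −1.38 ± 0.66 (adjusted p = 0.509). For H2-D1, H2-Eb1, H2-Ab1 and S100a9 the estimates were −2.18 ± 0.53, −3.43 ± 0.85, −2.88 ± 0.80 and −4.55 ± 0.98, with adjusted p = 0.367, 0.367, 0.391 and 0.367.

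As lists, chemokines and their receptors responded lower in aged mice (7 of 27 above 0, median −1.52 (−1.36 with bounds), adjusted p = 0.0111, adjusted p = 0.273 with estimated correlation), with medians of 0.80 in young and −0.63 in aged mice. Angiogenesis factors did as well (9 of 29 above 0, median −1.15 (−0.60 with bounds), adjusted p = 0.0472, adjusted p = 0.525 with estimated correlation), with medians of 0.80 and −0.19. Other lists with a lower response were disease-associated microglia, antigen presentation, lipid handling, cell cycle, monocytes and neutrophils, with 5 of 23, 1 of 19, 2 of 26, 5 of 28, 0 of 13 and 1 of 11 members above 0 and medians of −1.18, −0.95, −1.36 (−1.07 with bounds), −2.23 (−2.05 with bounds), −5.35 and −3.49 (−3.15 with bounds). The tests had adjusted p from 5.35e-09 to 0.0363, adjusted p from 0.213 to 0.653 with estimated correlation. Camera, which ranks a list against the other genes, called a higher response for homeostatic microglia, immediate early and dissociation genes, astrocytes, oligodendrocytes and choroid plexus, with 15 of 16, 12 of 24, 6 of 9, 7 of 7 and 5 of 6 members above 0 and medians of 0.41, 0.02, 3.15, 1.41 and 7.74 (7.02 with bounds). Their tests had adjusted p from 5.51e-15 to 0.00214, adjusted p from 0.213 to 0.525 with estimated correlation. The median interaction of all genes was −0.36, and immediate early and dissociation genes had medians of 0.89 in young and 0.75 in aged mice, so their response was not higher in aged mice in itself. Members called over the list alone were 1 lower of chemokines, 5 lower of antigen presentation, 4 lower of monocytes, 8 lower of neutrophils, 3 higher of immediate early and dissociation genes, 1 higher of astrocytes and 4 higher of choroid plexus. The 13 other tested lists were not called (adjusted p from 0.127 to 0.886).

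The 0 genes are from edgeR, with 1242 at an unadjusted p under 0.05, 278 called by DESeq2 and 2 without young sham 1. List calls ended without aged sham 2 for homeostatic microglia, angiogenesis, lipid handling, cell cycle (median 0.06, 0.00 with bounds) and oligodendrocytes; without aged dMCAO 1 for homeostatic microglia, disease-associated microglia, antigen presentation, angiogenesis, lipid handling, cell cycle and immediate early and dissociation genes (median −0.25); without young sham 1 for disease-associated microglia, angiogenesis, cell cycle and immediate early and dissociation genes (median −0.42); without young dMCAO 2 for disease-associated microglia, angiogenesis and lipid handling; without aged sham 1 for disease-associated microglia, chemokines and angiogenesis; without aged dMCAO 2 for chemokines, with adjusted p from 0.0516 to 0.910. The lists of monocytes, neutrophils, astrocytes and choroid plexus kept their calls in all 8 such fits. With the block by N code calls were lost for homeostatic microglia, antigen presentation, angiogenesis, lipid handling, cell cycle, immediate early and dissociation genes (median −0.08), astrocytes and oligodendrocytes, with adjusted p from 0.0513 to 0.531.

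Across 11955 genes, dMCAO log2 fold changes in young and aged mice correlated with Pearson's r = −0.0219 and Spearman's rho = −0.00590. This only describes, since genes are not replicates. Spp1 was called higher at both ages, 1 shared gene against 8.36e-05 expected by chance. Of the 160 genes higher in the 4 young libraries alone, 110 (68.8%) were above 0 in aged mice, against 40.0% of all genes. That share of all genes is not matched for expression. In aged mice the log2 fold change for dMCAO rose with mean expression (rank correlation 0.227). The 160 genes had medians of 1.52 in young and 0.78 in aged mice. There 45 had an unadjusted p under 0.05 in the same direction and 8 in the opposite one. Their interaction had a median of −1.001, with 0 called. Chosen in young libraries, these genes favour a larger young response, so a weaker aged one is not shown. Of 13 lower genes, 5 were lower in aged mice, against 59.4% of all genes.

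**Figure D2:**
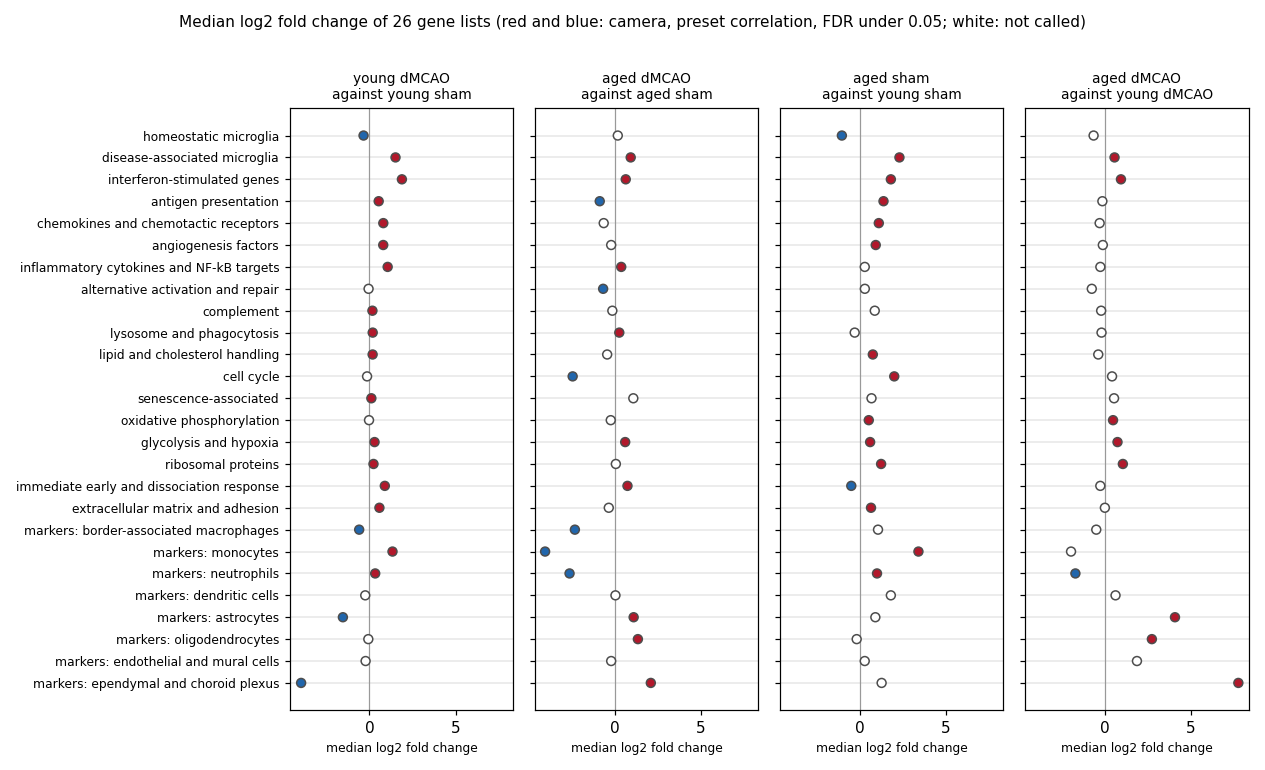
Median log2 fold change of 26 gene lists in the 4 comparisons of 2 groups, with genes that had no counts in a group set at their bound. Red points are lists called up, blue points lists called down and white points lists not called; chemokines had medians of 0.80, −0.63, 1.11 and −0.30 in the order young dMCAO against sham, aged dMCAO against sham, aged against young sham and aged against young dMCAO.

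Averaged over both surgeries, the comparison asked what distinguished the 4 aged from the 4 young libraries. In edgeR 89 genes were higher and 68 lower. Of the 89 higher genes, those named by size, level and lack of overlap between libraries were Dsg2, a protein of desmosomes (5.42 ± 0.99), Enpp2 (4.79 ± 0.51), Cdr2 (3.56 ± 0.66), the fatty acid elongase Elovl6 (3.30 ± 0.56) and Ezr, which ties membrane to actin (3.26 ± 0.42). Nedd4, a ubiquitin ligase (2.91 ± 0.44), Ifi27l2a (2.85 ± 0.39), the transcription factor Bhlhe40 (2.82 ± 0.53), Hlcs, which attaches biotin (2.71 ± 0.52), and Mbp (2.43 ± 0.26) were named as well. Their adjusted p lay between 0.0300 and 0.0473, and all 4 aged libraries lay above all 4 young ones in each.

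Of the 68 lower genes, those named by the same rule were Gpr165, Clcf1, Sgsh, Ccl2, Cmya5, Slc38a6, Rbm12, Btaf1, Trmt2a and Zdhhc14, with adjusted p between 0.0300 and 0.0473 and all 4 aged libraries below all 4 young ones. Gpr165, an orphan receptor, averaged 57.5, 30.8, 6.03 and 0 CPM in young sham, young dMCAO, aged sham and aged dMCAO. In the same order, the cytokine Clcf1 averaged 26.9, 33.99, 14.7 and 0 CPM, Sgsh, which breaks down heparan sulfate, 31.6, 26.9, 21.7 and 0 CPM, and Ccl2 65.1, 94.1, 41.2 and 0.715 CPM. Gpr165, Clcf1 and Sgsh were listed at 0 in both aged dMCAO libraries, where 3 counts would be 4.29 and 3.28 CPM, so their fall there is only a bound. Btaf1, Trmt2a, a transfer RNA methylase, and Zdhhc14, a palmitoyl transferase, had log2 fold changes of −2.45 ± 0.27, −2.29 ± 0.34 and −2.28 ± 0.39. Cmya5, Slc38a6 and Rbm12 averaged 1.26, 1.09 and 1.81 CPM in aged dMCAO and 60.5, 54.4 and 39.0 CPM in young dMCAO. By the shares given above, Malat1 was lower in all 4 aged than in all 4 young libraries, and Rn45s and Lars2 were higher in 3 of the 4, so these signs of RNA quality, untested as causes, went with age.

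Homeostatic genes fell with age (1 of 16 above 0, median −0.88, adjusted p = 2.00e-06, adjusted p = 0.380 with estimated correlation), with 9 lower over the list alone and 2 over all genes, P2ry13 (−1.36 ± 0.20) and Gpr34 (−1.61 ± 0.23). Disease-associated genes rose (20 of 23 above 0, median 1.52, adjusted p = 1.76e-13, adjusted p = 0.102 with estimated correlation), 12 of them over the list alone and 5 over all genes. These were Fabp5, a fatty acid carrier (3.58 ± 0.57), Lpl (2.17 ± 0.30), Clec7a (2.16 ± 0.39), Axl (2.10 ± 0.38) and Spp1 (1.85 ± 0.34). Interferon-stimulated genes rose (25 of 27 above 0, median 1.40, adjusted p = 1.76e-13, adjusted p = 0.102 with estimated correlation), 11 over the list alone and 2 over all genes, Ifi27l2a and Oasl2 (2.17 ± 0.42). Glycolysis rose (16 of 22 above 0, median 0.67, adjusted p = 1.43e-05, adjusted p = 0.102 with estimated correlation), 7 over the list alone and 2 over all genes, Pkm (1.495 ± 0.19) and Aldoa (1.30 ± 0.22). Ribosomal protein genes rose (44 of 46 above 0, median 1.14, adjusted p = 1.10e-43, adjusted p = 0.102 with estimated correlation), 42 over the list alone and 16 over all genes, among them Rps6 (1.49 ± 0.21), Rplp0 (1.43 ± 0.21) and Rpl4 (1.34 ± 0.20).

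The other lists of cell state higher on average were antigen presentation, angiogenesis, lipid handling, oxidative phosphorylation and extracellular matrix, with 14 of 19, 19 of 29, 15 of 26, 31 of 39 and 17 of 26 members above 0 and medians of 0.72 (1.01 with bounds), 0.70, 0.21 (0.24 with bounds), 0.53 and 1.21 (1.33 with bounds). Camera gave adjusted p from 0.000252 to 0.0436, adjusted p from 0.265 to 0.547 with estimated correlation. Markers of other cells higher on average were monocytes, astrocytes, oligodendrocytes and choroid plexus, with 9 of 13, 7 of 9, 5 of 7 and 5 of 6 members above 0 and medians of 1.004, 2.48, 0.64 (2.43 with bounds) and 5.33 (4.25 with bounds). With these came adjusted p from 9.29e-13 to 0.0219, adjusted p from 0.102 to 0.564 with estimated correlation. Medians under the 2 surgeries had opposite signs for antigen presentation, angiogenesis, lipid handling and monocytes, with medians after dMCAO of −0.14, −0.11, −0.53 (−0.38 with bounds) and −1.95, and for oligodendrocytes (−0.17 in sham). Over the list alone, members called were 2 higher and 1 lower of antigen presentation, 3 higher of angiogenesis, 4 higher and 2 lower of lipid handling, 1 higher and 1 lower of extracellular matrix, 3 higher of monocytes, 6 higher and 1 lower of astrocytes, 3 higher of oligodendrocytes and 5 higher of choroid plexus. Ttr rose by 5.49 ± 0.63. Among single genes, Mertk, a receptor for dying cells, and the cholesterol transporter Npc1 fell (−1.48 ± 0.23 and −1.82 ± 0.27), as did Hspa1b and Hspa1a (−1.45 ± 0.24 and −1.28 ± 0.23), and Vim rose by 2.59 ± 0.50. Chemokines were not called (17 of 27 above 0, median 0.15, adjusted p = 0.431, adjusted p = 0.564 with estimated correlation), and neither were 11 other lists (adjusted p from 0.0510 to 0.743 over the 12).

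At an unadjusted p under 0.05 there were 2528 genes. The count was 0 without young sham 1, young dMCAO 1 or young dMCAO 2 and 2 without young sham 2, against 377 without aged sham 1, 840 without aged sham 2, 1008 without aged dMCAO 1 and 855 without aged dMCAO 2. Within the surgeries it was 0 in sham and 9 after dMCAO, DESeq2 called 1370 genes. List calls ended without aged sham 2 for antigen presentation, lipid handling (median −0.36, −0.03 with bounds), extracellular matrix and monocytes (median −0.41); without aged dMCAO 2 for antigen presentation, angiogenesis (median −0.15, 0.50 with bounds), lipid handling (median −0.63, 0.36 with bounds), extracellular matrix (median −0.34, 0.20 with bounds) and monocytes (median −0.42, 1.40 with bounds); without young sham 1 for lipid handling, extracellular matrix, monocytes and oligodendrocytes; without young sham 2 for lipid handling; without young dMCAO 1 for lipid handling and oligodendrocytes; without aged sham 1 for extracellular matrix and oligodendrocytes; without young dMCAO 2 for monocytes, with adjusted p from 0.0507 to 0.433.

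Averaged over both ages, the comparison asked what dMCAO changed in all 4 injured against all 4 sham libraries. Spp1, Cst7 and Lpl rose. Spp1 averaged 3.42, 222, 20.5 and 496 CPM in young sham, young dMCAO, aged sham and aged dMCAO (log2 fold change 5.34 ± 0.38, adjusted p = 0.00250). In the same order Cst7 averaged 2.02, 86.2, 13.1 and 153 CPM (4.48 ± 0.43, adjusted p = 0.0146) and Lpl 10.3, 74.1, 47.0 and 331 CPM (2.82 ± 0.31, adjusted p = 0.0301). Cst7 and Lpl lie on chromosome 2, 150570415 to 150578944 and chromosome 8, 68880491 to 68907448. All 4 dMCAO libraries lay above all 4 sham libraries for each of the 3. The next genes by p did not pass: Lgals3bp, a secreted galectin partner, had 2.04 ± 0.25 (adjusted p = 0.0522), and Igfbp5, which binds insulin-like growth factors, 4.28 ± 0.55 (adjusted p = 0.0647). Gpnmb had 5.62 ± 0.75 (adjusted p = 0.0734).

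Disease-associated genes rose (21 of 23 above 0, median 0.98, adjusted p = 1.03e-35, adjusted p = 0.0887 with estimated correlation), 13 of them over the list alone and 3 over all genes. Interferon-stimulated genes rose (26 of 27 above 0, median 1.49, adjusted p = 6.52e-21, adjusted p = 0.0895 with estimated correlation), 9 over the list alone, with Irf7 at 2.23 ± 0.44 and Ifi204 at 2.24 ± 0.43, both with adjusted p = 0.216. Angiogenesis factors were called up (16 of 29 above 0, median 0.08, adjusted p = 7.91e-05, adjusted p = 0.268 with estimated correlation), 2 over the list alone and Spp1 over all genes, and Hif1a had 1.01 ± 0.20 (adjusted p = 0.216). Inflammatory cytokines rose (17 of 22 above 0, median 0.69, adjusted p = 4.39e-08, adjusted p = 0.243 with estimated correlation), with 8 higher and 1 lower over the list alone. Also higher were the lists for lysosome, senescence, glycolysis, ribosomal proteins and immediate early and dissociation genes, with 20 of 28, 6 of 10, 15 of 22, 34 of 46 and 22 of 24 members above 0 and medians of 0.21, 0.61, 0.45, 0.17 (0.18 with bounds) and 0.80. They reached adjusted p from 6.32e-14 to 0.0133, adjusted p from 0.137 to 0.584 with estimated correlation. Lower were those for alternative activation and cell cycle, with 4 of 13 and 6 of 28 members above 0 and medians of −1.05 and −1.32 (−1.23 with bounds). These reached adjusted p = 0.0193 and 0.0310, adjusted p = 0.243 and 0.743 with estimated correlation. Members called over the list alone were 1 higher of lysosome, 3 higher of glycolysis, 4 higher of immediate early and dissociation genes and 2 lower of alternative activation. Chemokines were not called (13 of 27 above 0, median −0.35 (0.06 with bounds), adjusted p = 0.143, adjusted p = 0.320 with estimated correlation), with a test pointing up.

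Markers of other cells lower on average were border macrophages, neutrophils and choroid plexus, with 1 of 11, 1 of 11 and 0 of 6 members above 0 and medians of −1.43 (−1.41 with bounds), −1.59 (−1.20 with bounds) and −1.81 (−1.10 with bounds). They carried adjusted p from 0.000213 to 0.0133, adjusted p from 0.243 to 0.387 with estimated correlation. Oligodendrocyte markers were higher on average (6 of 7 above 0, median 0.64, adjusted p = 0.00448, adjusted p = 0.260 with estimated correlation). Medians at the 2 ages had opposite signs for choroid markers (median 2.10 in aged mice), neutrophil markers (0.34 in young mice), oligodendrocyte markers (−0.06 in young mice) and angiogenesis factors (−0.19 in aged mice). Over the list alone, members called were 4 lower of border macrophages, 5 lower of neutrophils and 1 higher of oligodendrocytes. In total 11 tested lists were not called (adjusted p from 0.0512 to 0.990).

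In edgeR 3 genes were higher and 0 lower, with 1277 at an unadjusted p under 0.05, DESeq2 calling 320. The count was 0 without aged sham 1 or aged sham 2, 1 without young sham 2, young dMCAO 2 or aged dMCAO 2, and 16 without aged dMCAO 1. List calls ended without aged dMCAO 2 for angiogenesis (median −0.23, 0.05 with bounds), alternative activation, lysosome, cell cycle, senescence, ribosomal proteins, border macrophages and choroid plexus; without young sham 2 for alternative activation and cell cycle; without aged sham 1 for alternative activation, border macrophages and choroid plexus; without aged dMCAO 1 for alternative activation, cell cycle, border macrophages and choroid plexus; without aged sham 2 for lysosome, cell cycle, ribosomal proteins and oligodendrocytes; without young sham 1 for ribosomal proteins, with adjusted p from 0.0584 to 0.725. Without aged sham 2 the median of cell cycle was −0.07, −0.01 with bounds, and its test turned. With the block by N code the call ended for angiogenesis, with adjusted p = 0.0584. With thinned counts the choroid median was −0.81, 0.47 with bounds.

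Endothelial and mural cells and dendritic cells were called in none of the 7 comparisons (adjusted p from 0.0511 to 0.990). The lists with under 5 tested members were given no test: T and NK cells (3), B cells (2), neurons (4), erythroid cells (0), nuclear RNA (2) and sex-linked genes (4). Their members were called in none of the 7 comparisons over all genes.

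**Figure D3:**
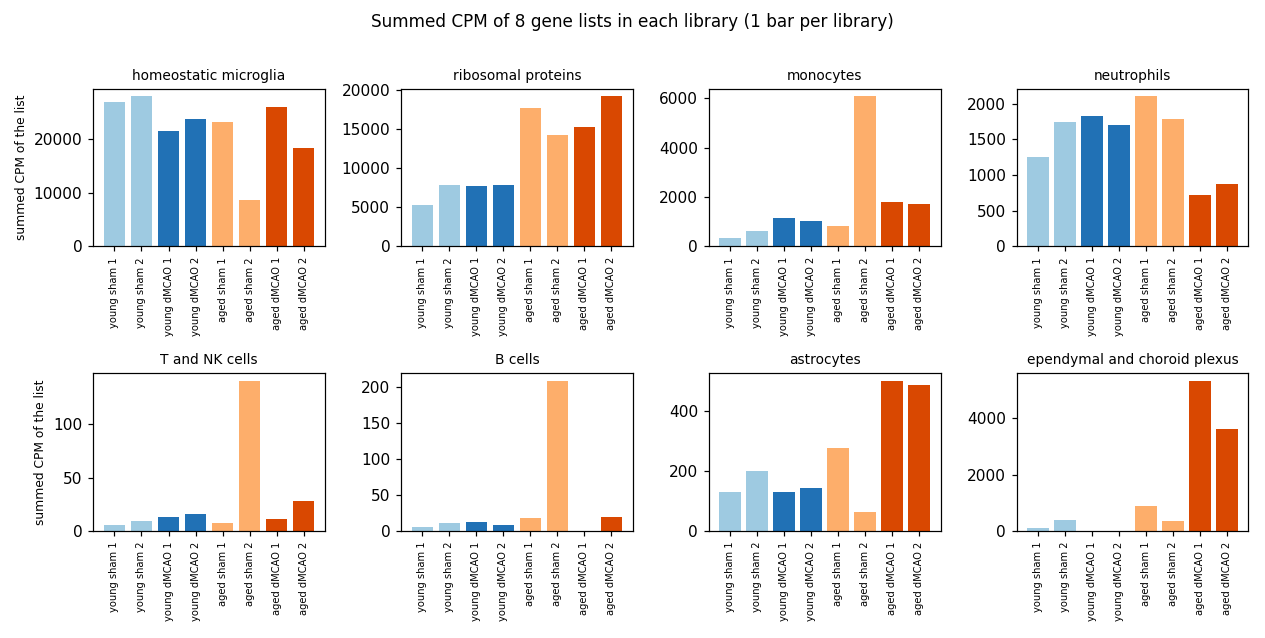
Summed CPM of the members of 8 gene lists in each of the 8 libraries, by group. The ribosomal protein genes summed to 14299.5 to 19182 CPM in the aged and 5342 to 7835 CPM in the young libraries, and monocyte markers reached 6079.6 CPM in aged sham 2.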

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

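Of the tests described here, those of thinned counts and of a lower share of microglia in aged sham 2 were chosen only after the result was seen. For 13 lists the response to dMCAO differed between the ages in the camera test of the interaction itself, which ranks a list against the other genes, whose median interaction was −0.36. Median interaction log2 fold changes, without bounds, were −1.52 for chemokines and their receptors, −1.15 for angiogenesis factors, −1.18 for disease-associated microglia, −0.95 for antigen presentation, −1.36 for lipid handling, −2.23 for cell cycle, −5.35 for monocyte markers and −3.49 for neutrophil markers. They were 0.41 for homeostatic microglia, 0.0230 for immediate early and dissociation genes, 3.15 for astrocyte markers, 1.41 for oligodendrocyte markers and 7.74 for ependymal and choroid plexus markers. With an estimated correlation 0 of the 13 held (adjusted p from 0.213 to 0.653).

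The first pattern is the 157 genes called between aged and young mice. Chance is argued against, though 35 splits allow no smaller share than 1 of 35. A fit of 2 groups called 118 genes for the real split of the 8 libraries. It called 0 for the other 34 splits, so 1 split gave as many. Unequal library totals are argued against as the whole cause, since 146 of the 157 genes (93.0%, 95% interval 87.9 to 96.0) were still called in the same direction with all libraries thinned to the smallest total, but the low depth of 3 of the 4 aged libraries, with whatever made them shallow, cannot be told apart from age, because the 1 deep aged library, aged sham 2, stands apart in monocyte genes: of the 200 genes with the smallest p in the 3 shallow libraries, 74% (95% interval 67.3 to 79.9) had the same direction in the deep one, against 56.4% of all genes. Gene length may contribute, since the genes called lower had a median exon length of 7302 bases against 5780 in random sets of like expression (percentile 99.05), and those called higher 2638 against 5773, though over all 11533 genes with a length the rank correlation of length with the log2 fold change was only −0.0198. For the ribosomal protein genes within the pattern, length and expression level are argued against by a median above all 10000 matched random lists (1.14 against at most 0.802, percentile 100), unequal totals by a median of 1.22 after thinning, and low depth by a median of 1.00 in the deep aged library against −0.58 to 0.22 in the young ones, while leukocyte RNA in that library and age itself stay open, as untested.

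The second pattern is the choroid plexus genes in aged dMCAO. Counting noise in the shallow libraries is argued against, since the lower 95% bound for Ttr was at least 2959 CPM in aged dMCAO, against an upper bound of at most 10.7 CPM in young dMCAO. Choroid plexus cells or their RNA are a candidate source: of 19 further choroid genes listed before their values were seen, 10 were tested and all 10 were above 0 in aged against young dMCAO, with a median of 6.72 (5.25 with bounds), and 2 of the 19 were expressed at 10 CPM or more in young sham. Their sum was 506 and 298 CPM in aged dMCAO but also 469 CPM in aged sham 2, against 75.7 to 124 CPM in the other 5 libraries. The sort gate named for these samples, intermediate CD45 with CD11b, would remove epithelial cells though not free RNA, and a response of aged microglia to dMCAO stays open, as untested.

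The third pattern is the monocyte genes in aged sham 2, which no group of the design explains, so that no biological explanation was tested. A lower share of microglia with every other cell type raised alike is argued against, because 22 markers of astrocytes, oligodendrocytes and choroid plexus had a median log2 ratio of −0.98 to the mean of the other 7 libraries, where 13 monocyte markers had 4.18. Blood leukocytes or their RNA are a candidate source: 19 of 19 further leukocyte genes, listed after the monocyte markers but before their own values were seen, were above 0 in that library, with a median of 3.50, and 10 of the 19 were expressed at 10 CPM or more in young sham. Among the most abundant, Lyz2 stood at 4045 CPM against 137 to 679 CPM elsewhere, Ahnak at 2555 against 31.5 to 306, and Coro1a at 656 against 190.2 to 445, while 16 of 16 homeostatic genes were below 0 with a median of −1.18. The gate for intermediate CD45 would remove leukocytes with high CD45, and what got past it stays open.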

How the results depend on the processing

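Tests with sample weights, thinned counts, Rn45s or the 3 shallow libraries left out, the FPKM table less its young sham 1 column, or lists in only the 2 groups were chosen after the data were seen. Against 1 gene for dMCAO in young, 4 for dMCAO in aged, 0 for age in sham, 9 for age after dMCAO, 0 for the interaction, 157 for age averaged and 3 for dMCAO averaged, DESeq2 called 32, 1034, 384, 1207, 278, 1370 and 320. With no filter the calls were 32, 672, 322, 735, 210, 1052 and 242, in the same order. With limma-voom 5 counts moved, to 0 for dMCAO in young, 1 for dMCAO in aged, 3 for age in sham, 68 for age after dMCAO and 573 for age averaged. RLE factors gave 4 for age after dMCAO. With only the 2 groups there were 173 for dMCAO in young, 0 for dMCAO in aged and 0 for age after dMCAO.

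The replicate block gave 0 genes for dMCAO in aged, 3 for age after dMCAO and 88 for age averaged. The block by N code gave 15, 168, 116, 192, 25, 596 and 154 genes in the order above, 9 lists for dMCAO in aged and 6 for the interaction. The deviations of the libraries from their group means correlated from −0.0830 to 0.0867 over the 6 pairs of groups, with 0 above 0.1, so the replicate numbers do not pair the libraries, and the N codes disagree with the numbers. The correlation of the responses at the 2 ages was −0.0219, −0.0457 with the replicate block, −0.0670 with the block by N code, and from −0.0840 to 0.0157 with 1 library left out.

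On FPKM with a pseudocount of 1, genes called were 16 for dMCAO in young, 0 for dMCAO in aged, 27 for age in sham, 1044 for age after dMCAO, 9 for the interaction, 853 for age averaged and 12 for dMCAO averaged. With a pseudocount of 0.1 they were 7, 116, 26, 1689, 5, 754 and 5. With a pseudocount of 1 and no filter they were 14 for dMCAO in young, 0 for dMCAO in aged, 16 for age in sham, 157 for age after dMCAO, 2 for the interaction and 408 for age averaged. Less the young sham 1 column they were 78 for dMCAO in young, 0 for dMCAO in aged, 89 for age in sham, 37 for age after dMCAO, 58 for the interaction and 59 for dMCAO averaged.

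Sample weights gave 209 genes for dMCAO in young, 1 for dMCAO in aged, 491 for age in sham, 206 for age after dMCAO, 462 for age averaged and 22 for dMCAO averaged. Without the 3 shallow libraries, which leaves 1 aged library, 161 were called for dMCAO in young and 3495 for age in sham. Thinned to the smallest total, the calls were 1, 3, 0, 11, 0, 211 and 4, in the order above. The shallow libraries leave every comparison with an aged group with few counts per gene, and the cause of these and the earlier moves was not tested.

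With 1 library left out, the genes called ranged from 0 to 1 for dMCAO in young, 0 to 422 for dMCAO in aged, 0 to 4 for age in sham, 0 to 692 for age after dMCAO, 0 to 2 for the interaction, 0 to 1008 for age averaged and 0 to 16 for dMCAO averaged. The lists called ranged from 16 to 22, 8 to 18, 15 to 20, 9 to 12, 7 to 16, 10 to 19 and 7 to 17, against 20, 15, 15, 9, 13, 14 and 15 with all libraries. With an estimated correlation 4 lists held for dMCAO in young and 0 elsewhere. With fry 4 held for age averaged, 1 for dMCAO averaged and 0 elsewhere.

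Directions turned for 9 gene results. On FPKM with a pseudocount of 1 these were Gpnmb (−0.70) for dMCAO in young, Hif1a (−0.12) for dMCAO in aged, Spp1 for age in sham (−2.08) and age averaged (−1.01), and Gpnmb (2.17), P2ry13 (−0.38) and Spp1 (2.13) for the interaction. Less the young sham 1 column they were H2-K1 (−0.21) for dMCAO in young, Hif1a (−0.12) for dMCAO in aged, and H2-D1 (1.30) and P2ry13 (−0.19) for the interaction. For 6 list results the direction of the camera test turned, with the calls ended. The median itself changed sign in 23 of 808 values with 1 library left out, for 18 results, and in 10 of 1002 values under other settings, for 7 results. With bounds it did so in 14 of the 808. With no filter the medians were −0.04 for senescence, dMCAO in young (0.08 with bounds, adjusted p = 0.256), and −0.22 for oligodendrocytes, age averaged (0.73 with bounds, adjusted p = 0.103). Lipid handling, age averaged, had −0.11 with the replicate block (0.02 with bounds, adjusted p = 0.0512) and −0.01 with that by N code (0.10 with bounds, still called), and immediate early and dissociation genes −0.04 for the interaction with the replicate block, still called. Homeostatic microglia had a median of 0.00553 (adjusted p = 0.841) for dMCAO in young with the block by N code. For dMCAO in young, ribosomal proteins ranged from −0.0601 without young sham 1 to 0.531 without young sham 2, and neutrophil markers kept a median above 0, at 0.17, without young sham 1, where only the test turned (adjusted p = 0.993). Without aged dMCAO 2, 17 of 29 cell cycle genes had no counts in a group, so its medians there, −8.37, −8.40 and −4.07 for dMCAO in aged, the interaction and dMCAO averaged, are fits over zeros, and −2.26, −2.39 and −1.10 with bounds. They are the lowest of ranges that reach 0, 0.0618 and −0.0733 without aged sham 2. With bounds the ranges were −3.03 to 0.511, −2.97 to −0.00462 and −1.51 to −0.0132.

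Of 1810 values for 101 list results, 1452 kept their label, 352 were weaker and 6 turned. Of 3529 values for 177 gene results, 2740 kept it, 363 were weaker, 415 stronger and 11 turned. By setting, the list results that held numbered 4 of 101 with an estimated correlation, 5 with fry, 94 with no filter, 80 with the block by N code, 90 with thinned counts, and 95 to 101 with the replicate block, the strict filter and the other factors.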

Other observations

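In splits of the 8 libraries into 4 and 4, chance was left open for 2 results, both of lists. In these, 9 splits gave as many calls as the real 15 between aged and young (highest other 17), and 4 as many as the real 17 between dMCAO and sham (highest other 17). For genes between dMCAO and sham the splits decide nothing: the fit of 2 groups called 0 genes for the real split and so lost the 3 genes called above, and 35 of 35 splits had at least as many. The highest other, 118, was the split by age, which points to a structure of the samples.

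For 3 libraries the counts did not match their own FPKM column best. Over 7590 genes, the counts of young sham 1 correlated at 0.208 with their own FPKM column and at 0.6002 with that of young sham 2, a column that matched the counts of young sham 2 itself less well, at 0.420, so its library is in doubt too. The FPKM column of young sham 1 correlated at most at 0.269, with the counts of young dMCAO 2. The counts of aged dMCAO 1 and 2 correlated at −0.0663 and 0.00528 with their own columns and at 0.796 and 0.717 with each other's. The other 4 libraries correlated with their own columns at 0.492 to 0.798, and best with them. In young sham 1, Spp1 had 12 counts and 531 FPKM, and Gpnmb 1 count and 39.9 FPKM.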
